A study of Mus musculus with 8 samples.

How the data were processed

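RNA from Thy1-positive testis cells of mouse pups at postnatal day 4 was measured on 8 one-colour Agilent arrays, 4 from wild type (WT) animals and 4 labelled Glis3KO2, all on C57BL/6. Thy1 is a surface protein used to enrich spermatogonial stem and progenitor cells from the testis. Per the labels' protocols, 1.5 µl of total RNA from each sample was amplified with NuGEN's Ovation Pico WTA system, and 5 µg of the amplified cDNA was labelled with Cy3 by Agilent's SureTag kit. The series' design text names 3 testes per genotype, while the labels list 4 samples of each. Nothing in the labels says that the samples of a genotype came from separate animals, so the p-values measure the spread between these samples, which may be technical.

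The deposited scanner files were made with Agilent Feature Extraction 12.0.0.7, per the file headers, and hold for each spot an intensity on a linear scale that the software had background-subtracted and detrended within the array. The deposited files also hold median spot and local background intensities and flags for spots that are well above background, saturated or outliers. The series' deposited value table was equal to the processed intensity on 100% of spots of every array, so it is not an independent normalization. Its column medians ranged from 67.2 to 143.6 (linear, not centred).

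The intensities were taken as log2 of the processed signal minus each array's 75th percentile over non-control spots. Outlier-flagged spots were left out, between 73 and 109 per array, and spots of a probe were averaged. The files carry accessions but no gene symbols, so each probe was named through its RefSeq accession, without version, in a gene table of assembly GRCm38.p6. Of 41174 probes, 28223 matched 1 gene, 0 matched several and 12951 stayed unnamed. The probe annotation in the file headers is on mm9, and no coordinates are given. Probes well above background on at least 4 of the 8 arrays, whatever their group, were kept (36415 probes). The probe with the highest mean stood for its gene, which left 17508 genes, 6360 of them with more than 1 kept probe. Zbtb16 and Kit were not analysed here. The signal over background was similar across arrays, with 86.0% to 90.3% of spots well above background, and the number of arrays limits the precision.

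Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 27 lists, with the correlation estimated for each list and with fry beside it. A list's relative shift is the mean log2 difference of its members minus that of all other genes. The mean of a list per array, with each gene centred over the 8 arrays, was compared with a two-sided exact permutation test over the 70 ways of labelling 4 of the 8 arrays, whose smallest p is 0.0286. Where every array of a group lay at a signal not well above background, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

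The tests, the 27 lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Glis3 and Thy1, a fixed set of germ and somatic markers, the genes past the threshold with the largest change (or, where none passed, the 5 of smallest p in each direction), leaving out provisional symbols such as Gm, LOC and Rik names, and up to 4 members of smallest p from each list that camera called. It gave 63 genes, 22 of them with more than 1 kept probe. 1 of these genes is not reported here. Kept probes of Foxo1, Id4 and Kcnj8 differed in sign.

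The arrays lay on 2 slides, each scanned once. Replicates 1 and 3 of each genotype were on slide 1 and replicates 2 and 4 on slide 2. On both slides the WT arrays were at positions 1 and 2 and the Glis3KO2 arrays at positions 3 and 4, so position on the slide and genotype cannot be told apart. The replicate numbers in the labels were checked for pairing: deviations from the group mean correlated across genes at r = 0.16, 0.34, 0.18 and 0.13 for same-numbered arrays (genes are not independent replicates), all over the 0.1 set for calling the samples paired. WT replicate 3 with Glis3KO2 replicate 4 (r = 0.14) and WT replicate 4 with Glis3KO2 replicate 3 (r = 0.12) were over it too, so among replicates 3 and 4 the correlation does not single out the number. A fit with the replicate number as a block was therefore run beside the unblocked one.

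Alternatives were other background corrections and normalizations, filters on dim probes, thresholds and probe rules, blocks for slide and replicate number, other spread models, array weights, and each array left out in turn. The mean spot signal planned for the normexp background correction is not among the columns used here, so normexp (offset 50) took the median spot signal with the median background. The model was tested on simulated data with the real genes' means and spreads and 4 arrays per genotype. Of 100 genes changed 2-fold among 17508, 14 were recovered, and of 100 changed 8-fold, 95 were, with 2 false calls. A simulated list shifted by 1 on the log2 scale, with independent genes, was called, and 0 of the other 26 lists were. In the real lists the estimated correlation between genes ranged from -0.025 (FOXO and PI3K signalling) to 0.67 (genes used by germ cells in general). The simulation thus does not test false calls of lists whose genes are correlated.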

Results

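The arrays compared Thy1-positive testis cells of newborn WT mice with those of Glis3KO2 mice, in 4 samples of each at postnatal day 4. Glis3 is a zinc finger transcription factor of the GLI-similar family, and the series concerns its part in spermatogenesis. The 75th percentile of processed signal ranged from 243 to 533 units. In both genotypes replicates 1 and 2 were brighter (355 to 533) than replicates 3 and 4 (243 to 341). On the first principal component, which held 32.3% of the variance, WT replicates 3 and 4 lay at 69.1 and 60.03, and the other 6 arrays lay at or below 3.87. The second component held 20.1%. WT replicate 1 lay apart on it at 80.8, and all other arrays lay between -30.1 and 3.18.

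The targeted gene was examined first. Glis3 signal was lower in every Glis3KO2 array than in every WT array. Its log2 signal relative to the array's 75th percentile averaged -0.23 ± 0.95 in WT and -1.67 ± 0.49 in Glis3KO2 (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible). The WT values were -1.09, -1.01, 0.57 and 0.60 for replicates 1 to 4, and the Glis3KO2 values were -1.98, -2.18, -1.18 and -1.32. The difference of -1.43 (SE 0.45), a 2.70-fold lower signal, was present in 4 of 4 numbered pairs and within slide 1 (-1.32) and slide 2 (-1.54). It did not pass the threshold over all genes (limma adjusted p = 0.697), and without WT replicates 3 and 4, an alternative chosen after seeing the data, it was -0.62. Whether the single Glis3 probe kept lies in the deleted part is not given in the sources used here, so it may check nothing about the labels. Thy1, the surface protein used for the isolation, averaged 1.23 ± 0.89 in WT and 1.88 ± 0.54 in Glis3KO2, and its difference of 0.65 (SE 0.44) did not pass (limma adjusted p = 0.713) and was 0.23 without WT replicate 4.

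**Figure D1:**
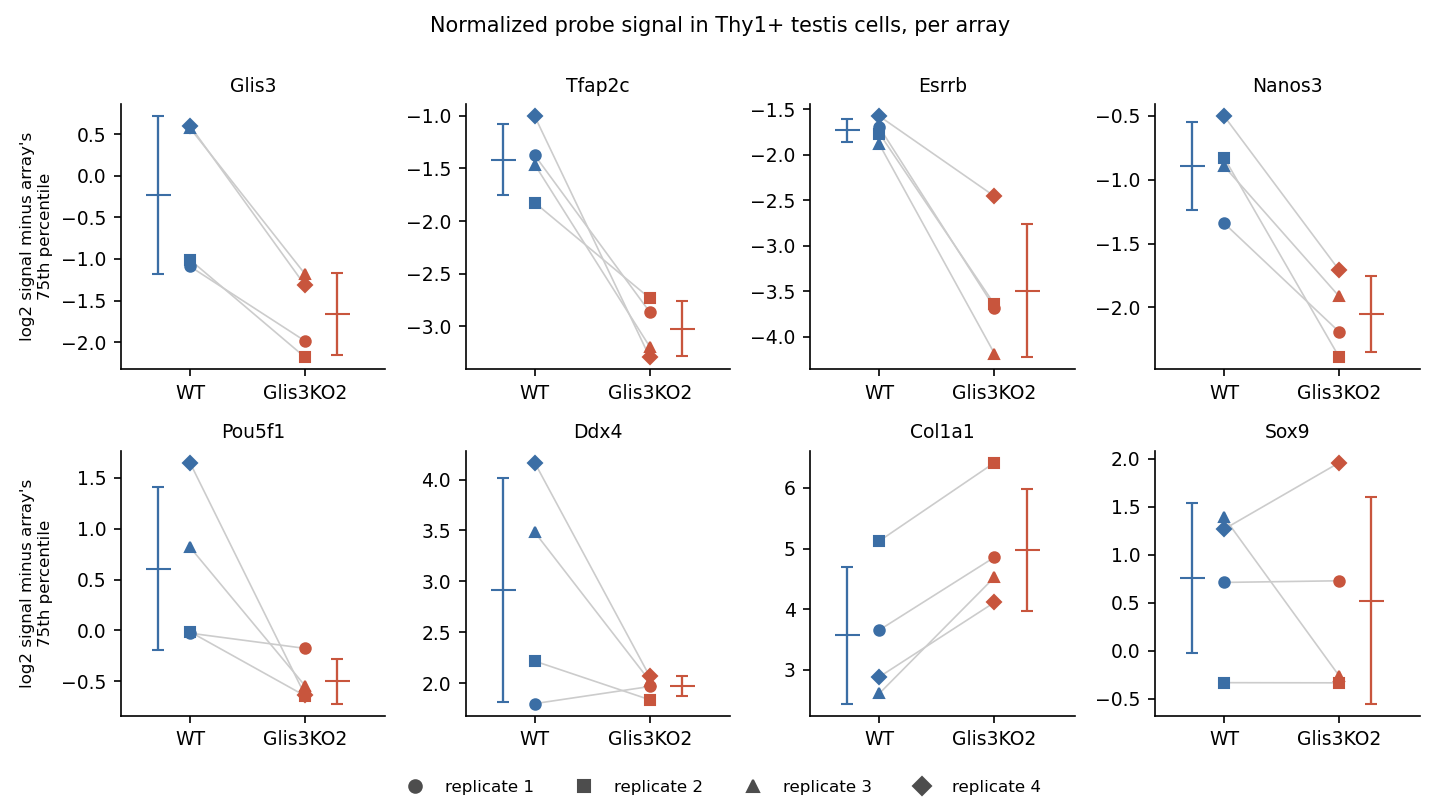
Log2 signal minus the array's 75th percentile for 8 genes in WT and Glis3KO2, with a marker for each array, grey lines joining arrays of the same replicate number, and bars for the mean and SD of 4 arrays. Glis3, Tfap2c, Esrrb, Nanos3 and Pou5f1 lay lower in all 4 Glis3KO2 arrays than in all 4 WT arrays, while Ddx4 was high in WT replicates 3 and 4 (3.48 and 4.17) and at 1.80 and 2.22 in WT replicates 1 and 2.

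The next question was which genes differed between the genotypes. Among the genes with the smallest p were Tfap2c, a transcription factor of germ cell specification, with a log2 difference of -1.61 (SE 0.25), Cps1, the mitochondrial carbamoyl phosphate synthetase of the urea cycle, with -1.89 (SE 0.30), Rfx8 with -1.74 (SE 0.30) and Hivep2 with -2.13 (SE 0.39). Trpm8, a cold-sensing ion channel, was not well above background on any Glis3KO2 array, and its WT signal was at least 1.60-fold higher. On the other side, Pcdh7, a protocadherin, had a difference of 2.23 (SE 0.38), Degs2, a sphingolipid desaturase and hydroxylase, 1.82 (SE 0.31), Mthfd2l, an enzyme of mitochondrial folate metabolism, 1.99 (SE 0.40) and Plcd3, a phospholipase C, 1.01 (SE 0.23). Adgrb3, an adhesion receptor, was not well above background on any WT array and at least 1.98-fold higher in Glis3KO2. None of these 10 genes passed the threshold, and each had its 4 Glis3KO2 arrays beyond all 4 WT arrays. Cps1 was well above background on 1 of 4 Glis3KO2 arrays, Rfx8 and Hivep2 on 3 of 4, and Mthfd2l on 3 of 4 WT arrays. These values moved with the background correction: with normexp and the 75th percentile 9 of the 10 genes moved by over 1.5 times, among them Mthfd2l to 0.18, Degs2 to 0.26, Plcd3 to 0.25, Trpm8 to -0.87 and Cps1 to -0.96, and Adgrb3 turned to -0.36. With normexp and quantile normalization all 10 moved by over 1.5 times without a change of sign, with Tfap2c at -0.78 and Trpm8 at -0.11. Without the filter on dim probes Adgrb3 was at 0.03, with the mean over a gene's probes Pcdh7 was at 1.22, and without WT replicates 3 and 4 Mthfd2l was at 1.31.

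Of 17508 genes, 0 were higher and 0 were lower at an adjusted p under 0.05 (limma). At an unadjusted p under 0.05 there were 1208, with 377 higher and 831 lower in Glis3KO2, where 875 are expected by chance. The share of lower genes among them depended on the scaling. It was 614 of 1078 with normexp and quantile normalization, 681 of 1117 with quantile normalization of log2 signal, and 1201 of 1641 with normexp and the 75th percentile. The smallest adjusted p, 0.0676, belonged to Gm16702, a predicted gene that the rule for named genes leaves out by its provisional name, and chosen after its values were seen. It was not well above background on any Glis3KO2 array and at least 1.95-fold higher in WT. Groups did not overlap for 613 genes (3.50%, against 2.86% by chance), of which 455 were lower and 158 higher. With the replicate number as a block, limma again called 0 genes, and 1877 had an unadjusted p under 0.05. Leaving out WT replicate 2 raised the unadjusted count to 2407, and leaving out WT replicate 3 lowered it to 663.

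Gene lists of germ cell states were compared next. The piRNA pathway list, genes that silence transposons in germ cells, fell with a relative shift of -0.67: 21 of its 21 measured members had a lower mean in Glis3KO2, 7 of them at an unadjusted p under 0.05. Tdrd9, a tudor domain helicase, had a log2 difference of -1.45 (SE 0.41), Fkbp6 -1.02 (SE 0.39), Piwil1 -0.97 (SE 0.29) and Tdrd6 -0.63 (SE 0.20). With normexp and quantile normalization Piwil1 was at -0.56 and Tdrd6 at -0.16, while Tdrd9 and Fkbp6 moved by less than 1.5 times. The list of genes used by germ cells in general fell by 0.49 relative to other genes, with 35 of 38 members lower. In that list the RNA helicase Ddx4 differed by -0.94 (SE 0.47), Piwil2 by -1.07 (SE 0.45) and the RNA-binding Dazl by -0.31 (SE 0.47). Camera's adjusted p was 3.75e-06 for the piRNA list and 5.08e-05 for the general list, and for each adjusted p = 0.792 with an estimated correlation.

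Genes of undifferentiated spermatogonia, the stem and progenitor cells of the male germ line, fell with a relative shift of -0.39, and 34 of 39 members were lower. Nanos3, an RNA-binding protein that keeps early germ cells alive, differed by -1.16 (SE 0.26), the transcriptional repressor Bcl6b by -1.37 (SE 0.34), the AKT co-activator Tcl1 by -0.96 (SE 0.27) and the adhesion molecule Cdh1 by -1.02 (SE 0.32). The pluripotency factor list fell by 0.45 relative to other genes, with 16 of 20 members lower. Esrrb, an orphan nuclear receptor of embryonic stem cells, differed by -1.76 (SE 0.34), Pou5f1, a pluripotency factor also made in early spermatogonia, by -1.11 (SE 0.37) and Fbxo15 by -1.89 (SE 0.61). Camera's adjusted p was 0.000103 for the spermatogonial list and 0.00482 for the pluripotency list, and for each adjusted p = 0.792 with an estimated correlation. The list of genes that GDNF, the niche growth factor of spermatogonial stem cells, induces in culture fell by 0.27, with 15 of 20 members lower (adjusted p = 0.0307, and adjusted p = 0.792 with an estimated correlation). It holds Pou3f1 at -0.84 (SE 0.29), Nanos2 at -0.998 (SE 0.37) and Egr2 at -0.98 (SE 0.42). The meiosis list fell by 0.29, with 22 of 26 members lower (adjusted p = 0.0476, and adjusted p = 0.792 with an estimated correlation), including Spag6 at -0.73 (SE 0.29), Mei1 at -0.81 (SE 0.37) and Mei4 at -1.06 (SE 0.58). With the replicate number as a block the GDNF list no longer passed (adjusted p = 0.0511), and with the slide as a block the meiosis list no longer passed (adjusted p = 0.0524). Under normexp with quantile normalization Spag6 was at -0.02, Cdh1 at -0.21, Mei4 at -0.38 and Pou3f1 at -0.47. Nanos2 was at -0.48 there, Fbxo15 at -0.68, Nanos3 at -0.69 and Esrrb at -0.73. Bcl6b, Tcl1, Pou5f1, Egr2 and Mei1 moved by a smaller factor.

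These 6 lists are not independent: 15 of 21 piRNA members measured, 16 of 20 GDNF, 25 of 39 undifferentiated, 18 of 38 general germ cell, 9 of 20 pluripotency and 3 of 26 meiosis members were also in another of the 27 lists. No member of them passed over all genes. Adjusted over the list alone, Tfap2c, Esrrb and Tcl1 passed in the pluripotency list (3 genes), Nanos3 and Bcl6b in the undifferentiated list (2 genes), Nanos3 in the general germ cell list (1 gene) and Bcl6b in the GDNF list (1 gene), while 0 passed in the piRNA and meiosis lists (7 and 2 members lower at an unadjusted p under 0.05). Cdh1 was well above background on 3 of 4 Glis3KO2 arrays, Spag6 on 2 of 4, and Ret on 3 of 4 WT arrays. Of 139 germ cell list members measured, 8 had every Glis3KO2 array below every WT array, and 0 the reverse, where chance gives 1.99 in each direction and the share of all genes with lower non-overlapping groups (2.60%) gives 3.61. These were Esrrb, Nanos3, Pax7, Piwil1, Pou5f1, Spag6, Tdrd6 and Tfap2c. The lists of differentiating spermatogonia (relative shift -0.15) and of DNA methylation enzymes (-0.04) did not pass, with adjusted p of 0.894 and 0.937 by camera. Other fixed germ cell markers did not pass over all genes: Etv5 differed by -0.79 (SE 0.40), Gfra1 by -0.59 (SE 0.33), Utf1 by -0.48 (SE 0.22), Stra8 by -0.57 (SE 0.38), Ret by -0.81 (SE 0.71), Id4 by -0.34 (SE 0.41), Sall4 by -0.30 (SE 0.31), Lhx1 by -0.29 (SE 0.24) and Foxo1 by 0.02 (SE 0.38). With the mean over a gene's probes Gfra1 was at -0.95 and Sall4 at -0.86, while Id4 was at -0.09 and Foxo1 turned to -0.21.

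The undifferentiated, piRNA and pluripotency list means were lower in Glis3KO2 in 4 of 4 numbered pairs, and the general germ cell, GDNF and meiosis means in 3 of 4. The differences were larger in pairs 3 and 4 than in pairs 1 and 2: by pair they were -0.04, -0.20, -0.75 and -0.81 for the undifferentiated list, -0.12, -0.57, -1.02 and -1.21 for the piRNA list and -0.17, -0.23, -0.55 and -1.10 for the pluripotency list. The centred mean of the general germ cell list was 0.76 and 1.20 in WT replicates 3 and 4, -0.58 and -0.27 in WT replicates 1 and 2, and between -0.67 and 0.03 in Glis3KO2. In replicates 1 and 2 the genotypes differed in this list by -0.12 and in replicates 3 and 4 by -0.99. Within slide 1 they differed by -0.28 and within slide 2 by -0.83. Without WT replicate 1 the relative shifts were larger, at -0.78 for the general germ cell list, -0.93 for piRNA, -0.47 for GDNF and -0.48 for meiosis. Without WT replicate 4 the general germ cell list (shift -0.20, adjusted p = 0.0691) and the pluripotency list (-0.30, adjusted p = 0.0568) no longer passed. Nor did the GDNF list (-0.16, adjusted p = 0.183) and the meiosis list (-0.07, adjusted p = 0.772). In that setting the piRNA shift was -0.41 (adjusted p = 0.00109) and the undifferentiated shift -0.26 (0.0120), both still past the threshold. With an estimated correlation 0 lists passed there (smallest adjusted p = 0.930). Ddx4 was at -0.53 there, Gfra1 at -0.39, Stra8 at -0.29, Sall4 at -0.17, Id4 at -0.14 and Ret at -0.35, and Dazl turned to 0.05. Without WT replicate 3, Nanos2 was at -0.64, Egr2 at -0.65, Mei4 at -0.64, Etv5 at -0.51, Ret at -0.45, Id4 at -0.07 and Dazl at -0.10. Without both of them 41 of the 63 named genes moved by over 1.5 times, with Ddx4 at -0.03, Piwil2 at -0.21, Fkbp6 at -0.31 and Pou5f1 at -0.48. The GDNF and meiosis lists were also lost without WT replicate 3 (0.177 and 0.213), without Glis3KO2 replicate 1 (0.0968 and 0.0802) or without Glis3KO2 replicate 2 (0.0630 and 0.186). Without WT replicates 3 and 4, an alternative chosen after seeing the data, camera called 0 lists (smallest adjusted p = 0.0877), and the relative shifts of the general germ cell, meiosis and GDNF lists turned to 0.18, 0.24 and 0.08. The meiosis list also missed the threshold with quantile normalization of log2 signal (0.0550) or of normexp values (0.0651), with no filter on dim probes (0.0769) and with the mean over a gene's probes (0.0632), and the GDNF list with the last of these (0.0651) and with normexp and the 75th percentile (0.215).

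Of the lists of somatic cells that such an isolation could hold, camera called 3 at its preset correlation, all higher in Glis3KO2, and 0 with an estimated correlation. The list of interstitial stroma, fibroblast-like cells and their extracellular matrix, rose with a relative shift of 0.92, and 34 of its 35 members were higher in Glis3KO2. Col1a1, a chain of type I collagen, differed by 1.41 (SE 0.61), the microfibril protein Mfap5 by 1.46 (SE 0.47), the calcification inhibitor Mgp by 0.91 (SE 0.39) and the Hedgehog effector Gli1 by 0.90 (SE 0.38). The peritubular and smooth muscle list rose by 0.77, with 22 of 24 members higher. In it the intermediate filament gene Des differed by 1.39 (SE 0.52), the smooth muscle co-activator Myocd by 1.60 (SE 0.70), Kcnj8 by 0.93 (SE 0.46) and the actin gene Acta2 by 0.76 (SE 0.34). The macrophage list rose by 0.40, with 21 of 25 members higher, among them Ly86 at 0.87 (SE 0.44), Aif1 at 0.77 (SE 0.52), H2-Aa at 0.75 (SE 0.49) and Cd74 at 0.73 (SE 0.50).

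Camera's adjusted p was 1.05e-14 for the stroma list, 2.46e-08 for the smooth muscle list and 0.00122 for the macrophage list, and for each adjusted p = 0.792 with an estimated correlation. In these 3 lists 0 genes passed over all genes or adjusted over the list alone (limma), while 4, 2 and 0 members had an unadjusted p under 0.05. The centred stroma mean was higher in 4 of 4 numbered pairs, by 0.64, 0.72, 1.07 and 0.998, and it differed by 0.85 within slide 1 and 0.86 within slide 2. The smooth muscle list was higher in 4 of 4 pairs too, and the macrophage list in 2 of 4, at -0.23 over replicates 1 and 2 and 0.91 over replicates 3 and 4. The macrophage call was lost without WT replicate 3 (shift 0.19, adjusted p = 0.0750), WT replicate 4 (0.15, adjusted p = 0.388) or Glis3KO2 replicate 1 (0.25, adjusted p = 0.135). Its shift was 0.70 without WT replicate 1 (adjusted p = 2.51e-08), and it turned to -0.29 without both WT replicates 3 and 4. In that setting the stroma shift was 0.32 (adjusted p = 0.0877) and the smooth muscle shift 0.19 (adjusted p = 0.383), so both calls were lost. Without Glis3KO2 replicate 2 the stroma shift was 0.62 (adjusted p = 3.20e-08) and Col1a1 0.93. Without WT replicate 4 Kcnj8 was at 0.53 and Cd74 at 0.44, and without WT replicate 3 Ly86 was at 0.50, Aif1 at 0.33 and H2-Aa at 0.36. Mfap5 was well above background on 1 of 4 WT arrays and turned to -0.40 with normexp and the 75th percentile. Thy1 is itself a member of the stroma list.

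**Figure D2:**
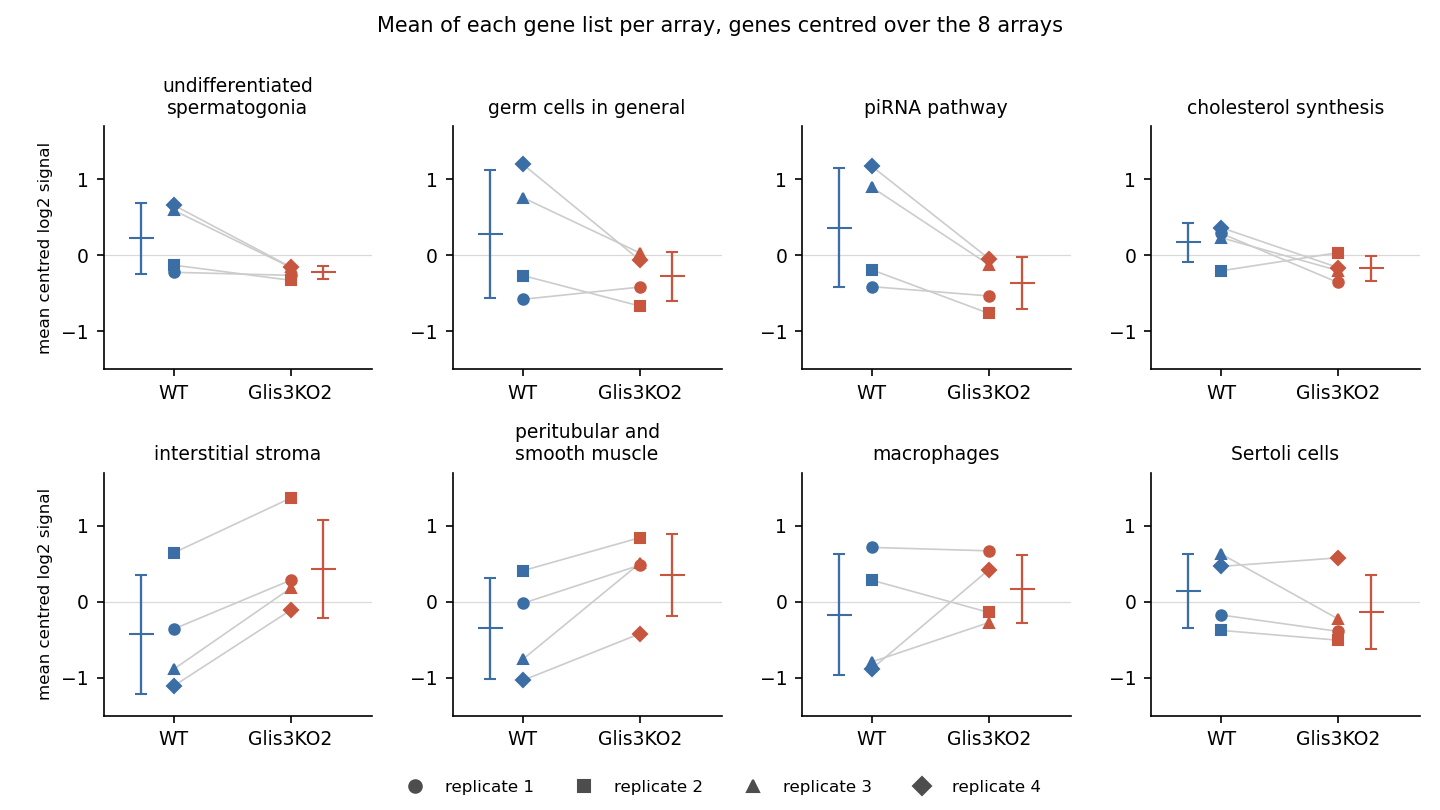
Mean log2 signal per array of 8 gene lists, each gene centred over the 8 arrays, with markers for arrays, grey lines joining arrays of the same replicate number, and bars for the mean and SD of 4 arrays. The stroma mean is higher in Glis3KO2 in 4 of 4 pairs, while WT replicates 3 and 4 reach 0.76 and 1.20 in the list of germ cells in general and the other 6 arrays stay at or below 0.03.

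Other somatic lists did not pass. The Sertoli cell list had a relative shift of -0.21 (adjusted p = 0.378), with Sox9, a transcription factor of Sertoli cells, at -0.24 (SE 0.55) and the hormone gene Amh at -0.16 (SE 0.21). It passed only where Glis3KO2 replicate 4 was left out (shift -0.45, adjusted p = 0.00948, and adjusted p = 0.683 with an estimated correlation). The Leydig cell and steroid synthesis list was at -0.00 (adjusted p = 0.937), with Cyp11a1 at -0.50 (SE 0.64) and Star at -0.16 (SE 0.37). The endothelial list was at 0.10 (0.716), with Pecam1 at -0.31 (SE 0.36). The lymphocyte list was at 0.23 (0.121), the erythroid list at -0.01 (0.937) and the list of epididymal and mesonephric epithelium at 0.31 (0.295). The lymphocyte list passed in 4 alternatives: with array weights (0.0151) and without WT replicate 1 (0.00632), WT replicate 2 (0.0177) or Glis3KO2 replicate 3 (0.00947). The endothelial list passed without WT replicate 1 (0.0480) and the epididymal list without Glis3KO2 replicate 4 (0.0431). With an estimated correlation in the same settings the adjusted p was 0.557 to 0.690 for the lymphocyte list, 0.446 for the endothelial and 0.683 for the epididymal list. Csf1r, a macrophage receptor, differed by 0.44 (SE 0.52).

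Among the process lists, cholesterol synthesis fell, with a relative shift of -0.28 and 17 of 22 members lower (adjusted p = 0.00431, and adjusted p = 0.792 with an estimated correlation). Dhcr7, a sterol reductase late in the pathway, differed by -1.005 (SE 0.29), the isomerase Idi1 by -0.89 (SE 0.29) and the decarboxylase Mvd by -0.61 (SE 0.24). Dhcr7 and Mvd had all Glis3KO2 arrays below all WT arrays, and 0 members passed over all genes or adjusted over the list alone (limma; 5 at an unadjusted p under 0.05). The list mean was lower in 3 of 4 pairs, and the call was lost without Glis3KO2 replicate 1 (adjusted p = 0.0566) or without WT replicates 3 and 4 (0.138), or with normexp and the 75th percentile (0.312).

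The remaining process lists did not pass in the unblocked fit. The relative shift was -0.17 for proliferation (adjusted p = 0.0950), -0.02 for p53 targets and apoptosis (0.941), 0.15 for FOXO and PI3K signalling (0.105), 0.12 for Hedgehog signalling with GLI and GLIS factors (0.269), 0.11 for retinoic acid metabolism (0.422), 0.04 for oxidative phosphorylation (0.716), 0.08 for glycolysis (0.488) and 0.12 for ribosomal proteins (0.121). Immediate early and heat shock genes, which respond to cell dissociation, were at 0.23 (0.0859). They passed with the replicate number as a block (0.0242, and adjusted p = 0.594 with an estimated correlation) or the slide as a block (0.0469, and adjusted p = 0.806 with an estimated correlation), with normexp and the 75th percentile (0.000265), and without WT replicate 2 (0.00437), Glis3KO2 replicate 1 (0.00795) or Glis3KO2 replicate 3 (0.0300). Proliferation passed in 5 alternatives: quantile normalization of log2 signal (0.0425) or of normexp values (0.0103), trend and robust (0.0469), array weights (0.00345) and without WT replicate 1 (0.00260). Normexp with the 75th percentile also gave calls, all higher, for FOXO (0.000650), oxidative phosphorylation (5.22e-05), glycolysis (0.00782) and ribosomal proteins (6.82e-07). Ribosomal proteins passed without Glis3KO2 replicate 3 (0.0231) or 4 (0.0431), and Hedgehog without Glis3KO2 replicate 4 (0.0431). None of these gained calls passed with an estimated correlation (adjusted p = 0.184 or more). The median, mean and test differed in sign for 4 lists that did not pass: Leydig, endothelial, retinoic acid and oxidative phosphorylation.

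Camera thus called 10 of the 27 lists, 7 lower and 3 higher. With an estimated correlation it called 0 lists and fry called 0, with 0 and 1 lists at an unadjusted p under 0.05. The exact permutation test on list means gave a smallest adjusted p of 0.726, with 1 list, pluripotency, at an unadjusted p under 0.05 (0.0286).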

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

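In 7 of 180 groups of 4 arrays tested, over the named genes and the list means, the highest or lowest array lay apart from the other 3, where chance gives about 1 in 20 groups. The tests in the paragraphs on cell composition, on Tfap2c, Esrrb and Nanos3 and on a swap between genotypes were chosen after the result was seen, and the test of a mislabelled sample before.

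Glis3KO2 replicate 4 had a Cyp11a1 signal of 0.51, and the nearest of the other Glis3KO2 arrays 0.85. WT replicate 2 had a Hivep2 signal of -2.29, against -1.51 for the nearest WT array. Glis3KO2 replicate 3 had a Tcl1 signal of -0.16, against -0.65 for the nearest. Tdrd6 was at -4.03 in Glis3KO2 replicate 4 and at -3.85 in the nearest. The list of epididymal and mesonephric epithelium had a centred mean of 0.32 in WT replicate 1 (nearest -0.24) and of -0.38 in Glis3KO2 replicate 4 (nearest 0.25). The ribosomal protein list was at 0.46 in Glis3KO2 replicate 2 (nearest -0.09).

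The germ cell lists were lower and the stroma lists higher in Glis3KO2. A lower share of germ cells alone would raise the markers of all other cell types alike. The stroma shift exceeded the Sertoli shift by 1.13 on average over the 4 numbered pairs (SD 0.53) and in 4 of 4 pairs. The stroma list was taken up for its rise on these same arrays, however, so the comparison cannot decide. A lower share of germ cells as the whole account stays open. A higher share of stromal cells stays open: that 97.1% of the 35 stroma members had a higher mean in Glis3KO2 restates the shift and cannot decide. The stroma shift was 0.68 in pairs 1 and 2 and 1.03 in pairs 3 and 4 (SD over pairs 0.21). Replicates 1 and 2 hold both genotypes, as do replicates 3 and 4. A difference between them that is common to both genotypes cancels from the shift by design, so these values do not test it. The size of the stroma shift does depend on WT replicates 3 and 4. Without them the relative shift fell from 0.92 to 0.32 and the call was lost (camera, adjusted p = 0.0877). That setting leaves only Glis3KO2 arrays among replicates 3 and 4. For the general germ cell list the shift was -0.12 in pairs 1 and 2 and -0.99 in pairs 3 and 4 (SD over pairs 0.60). A difference common to both genotypes cancels there too. With replicates 1 and 2 against 3 and 4 as a block the list kept its call by camera (adjusted p = 9.94e-08, and adjusted p = 0.536 with an estimated correlation). This block does not use the signal of each array. Being balanced over the genotypes it leaves the shift unchanged, so it does not test that difference as a cause. An effect on WT replicates 3 and 4 alone stays open. A change of gene activity within cells after loss of Glis3 stays open and was not tested apart from cell composition.

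Tfap2c, Esrrb and Nanos3 were lower in Glis3KO2 also in replicates 1 and 2. There their mean log2 shift was -1.44 (from -1.93 to -1.20), while the other 37 genes of the general germ cell list averaged -0.09 (SD over genes 0.46), the pluripotency list differed by -0.20 and the piRNA list by -0.35. A lower share of germ cells alone would give similar shifts. These 3 genes were picked on the same arrays for their small p, however, so the comparison cannot decide.

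WT replicates 1 and 2 lay close to Glis3KO2 in the germ cell lists, and not only there. Over all genes WT replicate 2 correlated at r = 0.951 to 0.963 with the Glis3KO2 arrays and at 0.925 to 0.937 with the other WT arrays. WT replicate 1 correlated most with Glis3KO2 replicate 1 (0.944), and with WT replicate 2 at 0.937. Arrays of different genotype correlated at 0.908 to 0.963, WT arrays with each other at 0.913 to 0.965 and Glis3KO2 arrays at 0.939 to 0.961. The lower of WT replicates 3 and 4 exceeded the highest Glis3KO2 array by 0.73 in the general germ cell mean (SD of Glis3KO2 0.32). No Glis3KO2 array thus reached WT replicates 3 and 4 in this mean. Glis3KO2 replicates 3 and 4 (0.03 and -0.06) lay above WT replicates 1 and 2 (-0.58 and -0.27) in it, however. Over all genes WT replicates 3 and 4 correlated with each other at r = 0.965. WT replicate 3 correlated with Glis3KO2 replicates 3 and 4 at 0.937 and 0.935, and with WT replicates 1 and 2 at 0.918 and 0.925. For WT replicate 4 these values were 0.943 and 0.941, and 0.913 and 0.933. Not every WT sample need resemble WT replicates 3 and 4, so a swap of WT replicate 1 or 2 with a Glis3KO2 array is not excluded. The next test took the 100 genes that best parted WT replicates 3 and 4 from Glis3KO2. In 25% of them both WT replicates 1 and 2 lay beyond every Glis3KO2 array on the WT side, against 6.67% by chance. That correct labels give over 50% was assumed before the test, and they need not where WT samples differ among themselves. Taken singly, WT replicate 1 lay beyond every Glis3KO2 array in 49% of these genes and WT replicate 2 in 44%, against 20% by chance. These chance shares assume arrays in random order. The genes were picked by small p, which favours Glis3KO2 values that lie close together and apart from WT replicates 3 and 4. That raises what chance gives, so the values cannot decide on the labels. The 25% is under the bound of 50% set before the test, and a mislabelled sample stays open. So does a difference in the composition of the WT samples, which was not tested separately.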

How the results depend on the processing

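Under every alternative the direction of Glis3 stayed lower in Glis3KO2, and it never passed over all genes: leaving out each array in turn gave -1.72 to -1.16 (adjusted p from 0.288 to 0.986). For genes, leaving out each array in turn gave 0 to 0 genes past the threshold, with 663 to 2407 at an unadjusted p under 0.05. Quantile normalization gave 1 gene, lower in Glis3KO2, and an adjusted p under 0.1 gave 1. In the other alternatives limma called 0 genes; testing all 36415 kept probes gave 0 with 2328 at an unadjusted p under 0.05, and array weights gave 0 with 2533. With the replicate number as a block limma called 0 genes (1877 at an unadjusted p under 0.05) and 10 lists. It lost the GDNF list, gained the dissociation list, and changed no other call. For the 62 other named genes no call changed in 1354 values, of which 21 turned in sign. Among the 63 named genes, 18 moved by over 1.5 times with normexp and the 75th percentile, 27 with normexp and quantile normalization, 12 with array weights, 17 without WT replicate 3, 15 without WT replicate 4 and 41 without both.

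Camera called 10 lists in the unblocked fit and 5 to 14 when each array was left out, with 5 without WT replicate 4. It called 0 with an estimated correlation, 0 without WT replicates 3 and 4, and 0 for the replicate block with an estimated correlation, and fry called 0 with and without the block. Leaving out WT replicates 3 and 4, blocking by brightness, and these 2 blocked tests were chosen after seeing the data. Blocking by brightness kept 10 list calls, and 0 with an estimated correlation (smallest adjusted p = 0.311). Each other alternative also gave 0 calls with an estimated correlation, a test added after seeing the data (smallest adjusted p = 0.184, with normexp and the 75th percentile). With normexp and the 75th percentile camera called 13 lists, 8 of them higher. That scaling moved the median of all genes to -0.23 from -0.08, so its shifts are read relative to it, and the cause was not tested in any case below. Quantile normalization of log2 signal and of normexp values kept 3 higher lists of 10. Of 648 list values, 532 kept direction and side, 53 lost the call (49 with the sign kept and 4 that turned), 25 gained one and 42 turned in sign. The series' value table moved nothing, being the same intensities. The number of arrays and the dimness of probes such as Trpm8 and Adgrb3 limit what can be read.

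Lists and genes that turned in sign, none of them past the threshold under that alternative, were as follows. With normexp and the 75th percentile, DNA methylation was 0.20, Leydig 0.031, endothelial -0.082, proliferation 0.094, p53 0.088, Adgrb3 -0.36, Mfap5 -0.40 and Star 0.067. With normexp and quantile normalization, oxidative phosphorylation was -0.016, and with quantile normalization alone erythroid was 0.025. With no filter, Leydig was 0.026 and p53 0.012. With array weights, Leydig was 0.046, p53 0.020, oxidative phosphorylation -0.0096 and Foxo1 -0.25. With the mean over a gene's probes, DNA methylation was 0.011, p53 0.0069 and Foxo1 -0.21. Without WT replicates 3 and 4, the shifts were 0.18 for germ cells in general, 0.16 for differentiating spermatogonia, 0.24 for meiosis, 0.081 for GDNF, 0.18 for Sertoli, -0.17 for endothelial, -0.29 for macrophage, -0.26 for lymphocyte, 0.059 for proliferation, -0.025 for dissociation and -0.0094 for glycolysis. In that setting Aif1 was -0.16, Amh 0.0099, Csf1r -0.39, Dazl 0.53, H2-Aa -0.16, Id4 0.36, Ret 0.41 and Sox9 0.33.

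Leaving out each array in turn, the shift ranged from -0.23 to 0.18 for Leydig, -0.19 to 0.11 for erythroid, -0.11 to 0.039 for p53, -0.023 to 0.29 for endothelial, -0.018 to 0.25 for Hedgehog, -0.077 to 0.093 for oxidative phosphorylation, -0.0021 to 0.12 for glycolysis, -0.027 to 0.17 for ribosomal proteins and -0.095 to 0.023 for DNA methylation. For genes it ranged from -1.12 to 0.032 for Cyp11a1, -0.23 to 0.25 for Foxo1, -0.43 to 0.17 for Star, -0.67 to 0.046 for Dazl and -0.71 to 0.050 for Sox9.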

Other observations

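Of the tests in this part, those on counts without a block, and on germ cell members in splits that part the pairs, were chosen after the counts were seen, and those on motile cilia genes, on the count with the block, on germ cell members without overlap in all splits and on genes next to Glis3 before their results were seen.

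Motile cilia genes were looked at after Cfap43 (-1.92), Cfap45 (-1.71), Cfap52 (-1.97) and Efcab10 (-2.62), which serve the ciliary and flagellar axoneme, had been seen with log2 differences this far below 0 and lower values in 4 of 4 numbered pairs. None of the 4 passed over all genes (limma adjusted p = 0.697). A list of other motile cilia genes, written without these 4 and Spag6, had 52 measured members. Of these, 43 had a lower and 9 a higher mean in Glis3KO2, and 5 had an unadjusted p under 0.05. Their mean log2 signal was -2.05 ± 0.23 in WT and -2.41 ± 0.08 in Glis3KO2 (SD, n = 4 each; exact permutation p = 0.0857), lower in 4 of 4 pairs. That motile cilia genes fall as a group in Glis3KO2 is a hypothesis, with a relative shift of -0.30 that did not pass the exact test. Camera gave p = 0.000474 at the preset correlation, p = 0.0998 with an estimated correlation, and p = 0.0246 with an estimated correlation and the replicate number as a block. The list was taken up for low values of related genes on these same arrays, so these p-values are no independent support. It was not run with other background corrections or without WT replicates 3 and 4.

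Chance could not be excluded for the count of genes: 10 of the 35 splits of the 8 arrays into 4 and 4 gave at least the real 1208 genes at an unadjusted p under 0.05, and the highest other split gave 2592. The split of replicates 1 and 2 against replicates 3 and 4, which follows the brightness of the arrays, gave 2519 genes and 16 lists, so part of the structure of the samples follows it. With this split as a block, limma called 0 genes and 1712 had an unadjusted p under 0.05. For the 10 lists called by camera, 16 of 35 splits gave as many, with 18 in the highest other. Among labelled splits, 4 of 70 gave at least 8 germ cell members without overlap in a given direction, with 25 in the highest other, so chance could not be excluded there either. Among the 16 labelled splits that part all 4 numbered pairs, only the real one reached 8 and the highest other gave 4, but 16 are too few for a share under 0.05. With the replicate number as a block, the 8 splits that part all 4 numbered pairs are too few for a share under 0.05: the real split gave 1877 genes, 1 split reached that count, and the highest other gave 1116.

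Among the 40 measured genes nearest to Glis3 on its chromosome (20 on each side, order from assembly GRCm38.p6), 1 gene, Mamdc2, had an unadjusted p under 0.05, against 6.90% of all genes. This gave no sign of a segment of other strain origin around the locus. Genes in such a segment need not change in signal, however, so the count cannot exclude one.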
